A study of Ictidomys tridecemlineatus with 10 samples.

How the data were processed

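Polyadenylated RNA from the subfornical organ of thirteen-lined ground squirrels was sequenced in 10 libraries, 5 from Active animals and 5 from animals in interbout arousal (IBA). Per the labels' protocols, the organ was dissected by hand from brain slices, and libraries were made with an mRNA kit from total RNA of moderate to high integrity. The integrity of each single library was not given in the sources used here. The series' design text calls the libraries biological replicates. Groups and replicate numbers came from the sample titles.

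Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.7a, featureCounts from Subread 2.0.1, edgeR 3.38.4 and R 4.2.1 were used. The genome build, the annotation and the strand setting were not given in the sources used here, so genes that overlap, lie antisense or have near-identical copies may share reads and are uncertain. Per the file headers, the authors deposited normalised CPM for each library, a signal scaled with factors so that the column sums differed between libraries. The authors also deposited a log2 fold change and an average log2 CPM per gene, an F statistic, which is a score with no fixed range, and a p-value with its FDR. The authors' fold changes were coded Active minus IBA, and their sign was turned where they are compared. The authors' average log2 CPM differed from that of the 10 libraries by a median of 0.10, and the authors' p-values matched an F test with a median of 22.7 denominator degrees of freedom against 14.2 in an edgeR fit of the 10 libraries, so their fit was not rebuilt exactly, and whether it held further libraries is not known.

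In every library 100% of the CPM values were whole multiples of the value of 1 read, within 0.01 of a read. The recovered totals were 27927394, 24645145, 25622496, 20993093 and 30713168 reads for Active replicates 1 to 5 and 35382203, 25422147, 30186445, 24195342 and 27216112 for IBA replicates 1 to 5. A value of 3 reads, the limit that a count of 0 allows, was 0.0882 to 0.132 CPM. It covers counting error only. No 2 libraries of a state agreed within sampling noise.

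The deposited table listed 25964 genes, of which 430 were at 0 in every library. Genes with a mean of at least 1 CPM over the 10 libraries were tested, 15445 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(CPM + 0.5) with an intensity trend and no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 43 lists. Of these lists, 29 held pathways and 14 held cell type markers, matched by symbol. A list score is the mean over members of the log2 value minus the gene's mean over the 10 libraries. Genes under the filter were compared by an exact permutation test over 252 assignments. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives.

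The sample groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 2 CPM and no overlap between states. It also named 12 genes whatever their result (Agtr1, Nos1, Etv1, Scn7a, Trpv1, Trpv4, Adcyap1, Rxfp1, Pdyn, Fos, Rbm3 and Cirbp), and up to 2 risen and 2 fallen members of each list with a called gene. Of the 16 largest changes, 15 are described, and 1 is not used here. Other genes are said to be chosen after their values were seen. Alternatives changed the pseudocount, filter, scaling, variance model, sample weights, covariates, pairing and count model, and left out each library in turn. A choroid plexus covariate and the omission of Active replicates 4 and 5 together were added after the data were seen.

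On data simulated for the comparison of IBA with Active over 15445 genes, the test recovered 22.4% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 97.0% of those changed 4-fold, with 1 false call among 115. With no change simulated it made 0 calls. Smaller changes could thus pass unseen with 5 libraries per state. The simulation drew each gene on its own and left out variation that genes of a library share, so its false calls may be too few. Groupings of the real libraries that ignored state called up to 9 genes.

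Symbols were used as the table gave them. Of the 25964 names, 22416 matched a name in the reference list of the assembly mIctTri1.hap1, which was used for names only, and no coordinates are given. There were 26 names that a spreadsheet had turned into dates; 21 of them were tested and 0 called. Genes of respiratory complexes III and IV, and other list members with no matching symbol, were not analysed here. Checks of GC content and gene length were not run, since no gene sequence or length was used here.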

Results

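RNA was sequenced from the subfornical organ of thirteen-lined ground squirrels, a hibernating rodent. The subfornical organ is a small midline brain structure outside the blood-brain barrier whose neurons sense blood osmolality and angiotensin and drive thirst. The libraries fell into 2 states with 5 biological replicates each. Active animals were not hibernating. Interbout arousal (IBA) animals were in the hibernation season, in one of the periodic returns to normal body temperature between bouts of torpor. The series' title concerns suppressed neurons in this kind of organ and long survival without water, so the comparison asks which transcripts of the organ differed between the states. The normalised CPM values could be turned back into whole reads, which gave 20993093 to 30713168 reads per Active library and 24195342 to 35382203 per IBA library. No gene took more than 1.44% of any library's reads. Every fold change is IBA relative to Active on the log2(CPM + 0.5) scale, which understates changes of genes with low values.

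The libraries also differed in ways other than state. The first principal component held 29.1% of the variance and placed all 5 IBA libraries on one side of all 5 Active libraries, and the second held 19.9%. Choroid plexus markers were highest in Active replicate 4, with a list score of 2.36 against -0.91 to 0.19 in the other Active libraries. Its value for Ttr, the transthyretin gene that choroid plexus expresses strongly, was 10024 CPM, and the other Active libraries held 315 to 1625 CPM. Oligodendrocyte marker scores ranged from -1.32 to 0.60 in Active and from -1.42 to 1.13 in IBA libraries. Camera called neither list (adjusted p = 0.427 for choroid plexus, median log2 difference -0.22 with 12 of 15 lower in IBA, and 0.598 for oligodendrocytes, median 0.24 with 10 of 13 higher), and the spread within states leaves a difference possible.

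Single genes of several functions passed the test, among them a phagocyte gene and a cold-inducible gene that were higher in IBA and a developmental transcription factor that was lower. Gpnmb, a membrane glycoprotein of lysosome-rich phagocytic cells, rose most among the named genes, from 2.34 ± 0.497 CPM in Active to 12.98 ± 4.83 CPM in IBA (SD, n = 5 each), a fold change of 4.54. Rbm3, a cold-inducible RNA-binding protein, rose from 28.6 ± 7.64 to 78.2 ± 22.2 CPM. Sox8, a transcription factor of the SoxE group, fell from 5.58 ± 1.88 to 0.9747 ± 0.704 CPM.

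Of 15445 genes tested, 62 passed the threshold in limma, 34 of them higher and 28 lower in IBA. All 62 had no overlap between the values of the states, but they were called on these same values, so this adds no support. Among all genes tested, 6.38% had no overlap, where chance gives 0.794%. The rises had a median log2 fold change of 0.84 and the falls one of -0.94. An unadjusted p under 0.05 was found for 3685 genes, 1968 higher and 1717 lower, where chance gives 772 if genes are independent. Genes of a library vary together, and groupings of the libraries that ignored state gave a median of 622 and up to 2509. The direction of the split depended on scaling: 54.8% of the calls were higher in IBA with the deposited scaling, 41.9% after median-of-ratios scaling and 36.8% with every library scaled to the same total. edgeR's quasi-likelihood test on the recovered reads called 57 genes, 25 higher and 32 lower, and 51 of them were among the 62. DESeq2 on the same reads called 1527 genes, 596 higher and 931 lower, with all 62 among them.

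The number of calls and the genes called depended on single libraries. Without Active replicate 1, 2, 3, 4 or 5, limma called 7, 27, 51, 31 or 5 genes, of which 7, 13, 32, 25 and 5 were among the 62. Without IBA replicate 1, 2, 3, 4 or 5, it called 7, 4, 25, 15 or 245 genes, of which 6, 4, 18, 12 and 62 were among the 62. Without both Active replicate 4 and Active replicate 5, limma called 0 genes, with 2191 at an unadjusted p under 0.05. Many genes lay near the threshold, since 1195 had an adjusted p under 0.1 in the limma fit of all libraries. All 62 kept an unadjusted p under 0.05 in limma in each omission. They were chosen on these same libraries, so that is no separate support.

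**Figure D1:**
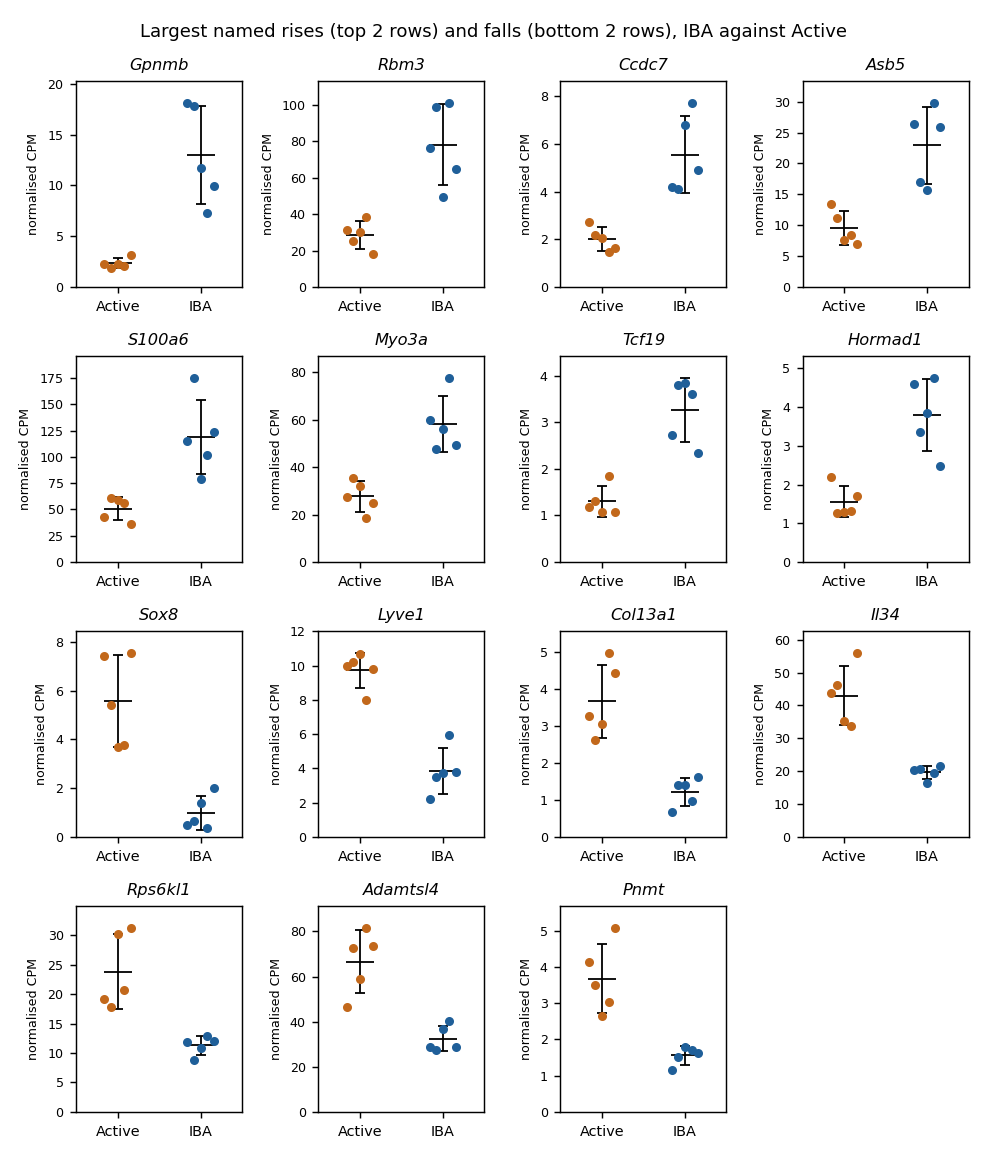
Normalised CPM (vertical axes, each starting at 0) of the 8 named genes with the largest rise and of 7 named genes with a large fall, for each state. Points are the 5 libraries of a state, and bars are the mean ± SD. In each gene the points of the states do not overlap, which the rule for named genes required, as for Gpnmb with means of 2.34 and 12.98 CPM.

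Behind Gpnmb and Rbm3, the named rises were of mixed function. S100a6, a small calcium-binding protein, rose from 50.9 ± 10.8 to 119.1 ± 35.6 CPM, with a log2 fold change of 1.20 (SE 0.20, adjusted p = 0.0347 in limma). Myo3a, an actin motor that carries a kinase domain, rose from 27.7 ± 6.47 to 58.1 ± 11.9 CPM. Asb5, a SOCS-box protein of the ubiquitin ligase adaptor kind, rose from 9.50 ± 2.75 to 22.9 ± 6.22 CPM. Ccdc7, Tcf19 and Hormad1, the last a protein of meiotic chromosome axes, rose by log2 fold changes of 1.25, 1.06 and 1.05 from Active means of 2.01, 1.30 and 1.56 CPM. The adjusted p of Gpnmb was 0.00579 and that of Rbm3 0.0347.

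The named falls included genes of the matrix, of macrophages and of signalling. Il34, a ligand of the receptor that keeps microglia alive, fell from 42.999 ± 8.99 to 19.7 ± 2.04 CPM, with a log2 fold change of -1.09 (SE 0.15, adjusted p = 0.0222 in limma). Lyve1, a hyaluronan receptor of lymphatic vessels and of macrophages along blood vessels, fell from 9.73 ± 1.01 to 3.85 ± 1.34 CPM. Adamtsl4, a secreted matrix protein, fell from 66.6 ± 13.9 to 32.4 ± 5.68 CPM, and Col13a1, a membrane-bound collagen, fell from 3.67 ± 0.990 to 1.22 ± 0.382 CPM. Rps6kl1, a kinase-like gene, fell from 23.8 ± 6.35 to 11.3 ± 1.55 CPM. Pnmt, the enzyme that turns noradrenaline into adrenaline, fell from 3.68 ± 0.954 to 1.56 ± 0.252 CPM. Sox8 had a log2 fold change of -2.11 (SE 0.32, adjusted p = 0.0347 in limma). Over 25 alternative settings its value ranged from -2.58 to -1.34. Other genes with low values also moved: Col13a1 from -1.63 to -0.81, Pnmt from -1.28 to -0.66, Tcf19 from 0.67 to 1.30 and Hormad1 from 0.70 to 1.25. Of these 15 genes, Gpnmb kept its adjusted p under the threshold in 25 of 26 alternative settings and Hormad1 in 9 of 25.

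Genes known for the thirst neurons of the subfornical organ did not pass the test. Agtr1, the angiotensin II receptor gene, was at 44.0 ± 19.4 CPM in Active and 50.4 ± 15.8 CPM in IBA, a log2 difference of 0.31 (95% interval -0.48 to 1.10). Without Active replicate 5, whose Agtr1 value was 13.6 CPM, the difference was -0.06. Etv1, a transcription factor of these neurons, was at 119.7 ± 25.3 and 124.5 ± 5.16 CPM, and its difference of 0.08 turned to -0.02 without the same library. Nos1, neuronal nitric oxide synthase, was at 2.88 ± 0.456 and 2.64 ± 0.564 CPM, and Pdyn, the prodynorphin gene, at 2.69 ± 0.793 and 3.29 ± 0.726 CPM. Fos, an immediate early gene of neuronal activity, was at 33.6 ± 21.7 and 30.5 ± 5.44 CPM, with a log2 difference of 0.01 (95% interval -0.61 to 0.64) that changed sign in 15 of 26 alternative settings.

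Channel and peptide genes also named in advance gave values without a call, and the cells that express them were not identified here. Scn7a, the sodium channel gene linked to sodium sensing, was at 653 ± 152 CPM in Active and 984 ± 219 CPM in IBA, a log2 difference of 0.60 (95% interval 0.16 to 1.03, adjusted p = 0.112 in limma). Trpv1, a cation channel gene tied to osmosensation, was at 3.96 ± 0.383 and 4.96 ± 0.612 CPM, a difference of 0.29 (adjusted p = 0.239). Adcyap1, which encodes the peptide PACAP, was at 12.99 ± 5.81 and 17.5 ± 3.98 CPM (adjusted p = 0.289). Trpv4 and Rxfp1 lay under the filter on low values. Trpv4 was at 0.972 ± 0.922 CPM in Active and 0.232 ± 0.166 CPM in IBA (n = 5 each, two-sided exact permutation p = 0.0238, smallest possible p 0.00794). Its highest value, 2.60 CPM, was in Active replicate 4, and the other Active libraries held 0.46 to 0.82 CPM. Rxfp1 was at 0.1998 ± 0.260 and 0.126 ± 0.155 CPM (exact permutation p = 0.611).

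**Figure D2:**
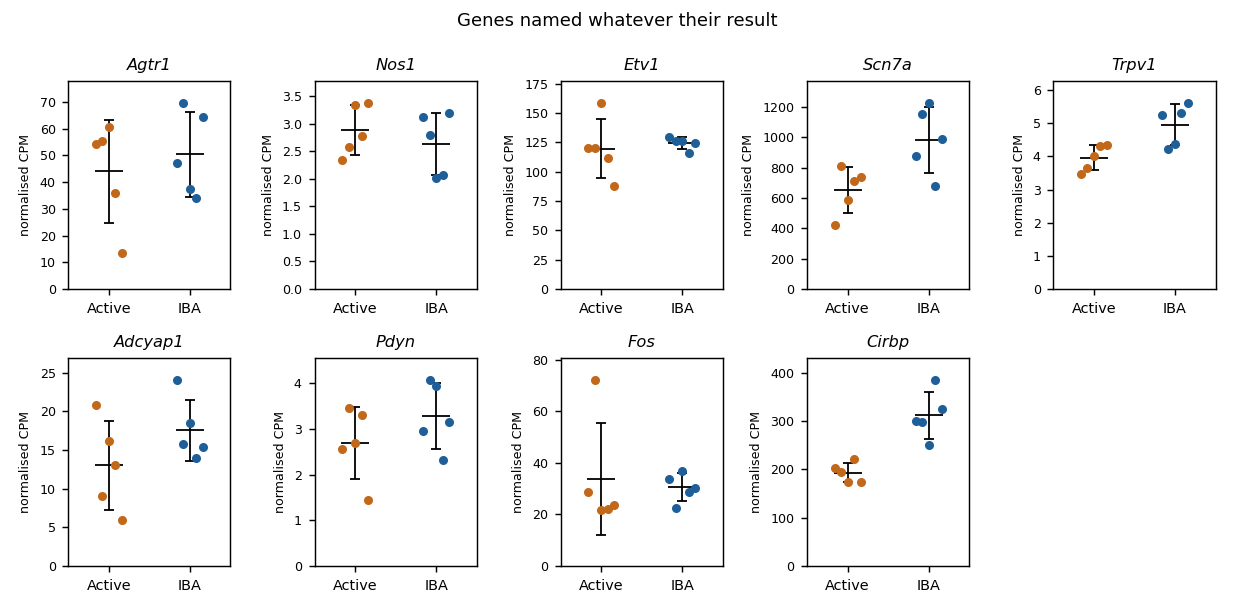
Normalised CPM (vertical axes, each starting at 0) of 9 genes named whatever their result, for each state. Points are the 5 libraries of a state, and bars are the mean ± SD. Cirbp alone among these 9 separated the states in the limma test, with means of 193.1 and 311.9 CPM.

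Of the 43 gene lists fixed before the data were examined, 4 held a gene that passed over all genes tested, and 2 of those are described. In the list of cold-inducible RNA-binding and heat shock proteins, 2 of 24 measured members rose and none fell. Cirbp, a cold-inducible RNA-binding protein like Rbm3, rose from 193.1 ± 20.1 to 311.9 ± 49.1 CPM, with a log2 fold change of 0.68 (SE 0.12, adjusted p = 0.0378 in limma). With p adjusted over the list alone, 10 members passed, 3 higher and 7 lower. The lower ones were chaperone genes and their regulator, among them Hspa4, Dnaja1, Hsph1 and Hsf1, with log2 differences of -0.46, -0.59, -1.10 and -0.67, named after their values were seen. The list as a whole was not called (camera adjusted p = 0.300, and adjusted p = 0.894 with an estimated correlation).

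Microglia and macrophage markers split in direction. Of 13 measured members, 2 rose, 1 fell and 10 did not pass over all genes tested. There were 5 higher and 2 lower when adjusted over the list alone, with these 3 among them. P2ry12, an ADP receptor of microglia, rose from 20.45 ± 1.85 to 39.0 ± 8.46 CPM, with a log2 fold change of 0.89 (SE 0.14). Tyrobp, a signalling adaptor of myeloid receptors, rose from 16.1 ± 1.81 to 28.1 ± 3.53 CPM, a log2 fold change of 0.78 (SE 0.12). Lyve1 was the member that fell. The adjusted p of each was 0.0347 in limma. The list as a whole was not called (camera adjusted p = 0.559, and adjusted p = 0.894 with an estimated correlation).

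Camera with its preset correlation called 4 lists, 2 higher and 2 lower in IBA, and called 0 with an estimated correlation. limma's fry called 0 lists after adjustment, with 5 at an unadjusted p under 0.05. Its mixed form, which counts members changing either way, called 21 lists. Among them were microglia and macrophage markers (adjusted p = 1.64e-05), cold-inducible and heat shock proteins (adjusted p = 5.03e-05), osmosensation genes (adjusted p = 7.06e-05) and pericyte markers (adjusted p = 0.00514). This form asks only whether members change, and 23.9% of all genes tested had an unadjusted p under 0.05 in limma. Its calls thus do not set these lists apart from other genes, and it was not run on regroupings of the libraries. All 54 measured cytosolic ribosomal protein genes had higher means in IBA, with a median log2 fold change of 0.55 (adjusted p = 1.22e-16, and adjusted p = 0.894 with an estimated correlation). None of them passed over all genes tested, and 46 passed when adjusted over the list alone. Active replicate 5 had the lowest score of this list, -0.80, and without it the median was 0.39. Nuclear-encoded oxidative phosphorylation genes had a median of 0.21, with 32 of 34 higher in IBA (adjusted p = 0.00169, and adjusted p = 0.894 with an estimated correlation). Without Active replicate 5 the median of this list was 0.13. None passed over all genes or adjusted over the list alone.

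Cholesterol synthesis genes and extracellular matrix genes were the lists called lower. For cholesterol synthesis the median log2 fold change was -0.19, with 14 of 21 lower (adjusted p = 0.0207, and adjusted p = 0.894 with an estimated correlation). Adjusted over the list alone, 5 were lower, among them Srebf2, the transcription factor of sterol synthesis, and Sqle, squalene epoxidase, with log2 differences of -0.95 and -0.78. This list was called in 20 of the 23 settings examined, and not with no filter on low values, without Active replicate 2 or without IBA replicate 3 (adjusted p = 0.131, 0.0998 and 0.111). The median was -0.29 without Active replicate 3 and -0.09 without Active replicates 4 and 5. For matrix and collagen genes the median was -0.20, with 23 of 34 lower (adjusted p = 0.0462, and adjusted p = 0.894 with an estimated correlation). When adjusted over the list alone, 4 were lower and 1 higher: Col5a1 and Fbln1 had log2 differences of -0.85 and -1.21, and Col12a1 one of 0.92. These members were named after their values were seen. Active replicate 5 had the highest matrix score, 0.55, and without it that list had a median of -0.12 and was no longer called (adjusted p = 0.114). Fibroblast and leptomeningeal marker scores moved in part with it. The lists share Col1a1, Col1a2, Col3a1, Dcn and Lum, so some agreement is built in. Active replicate 5 had a fibroblast score of 0.70. IBA replicates 1, 2 and 5 had -0.21, -0.33 and -0.34 beside matrix scores of -0.14, -0.21 and -0.18. IBA replicate 3 had a fibroblast score of 0.40 beside a matrix score of only 0.04. The matrix list was called in 12 of the 23 settings examined. Regroupings of the 10 libraries that ignored state called up to 16 lists, and 86 of 100 groupings called at least 4.

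**Figure D3:**
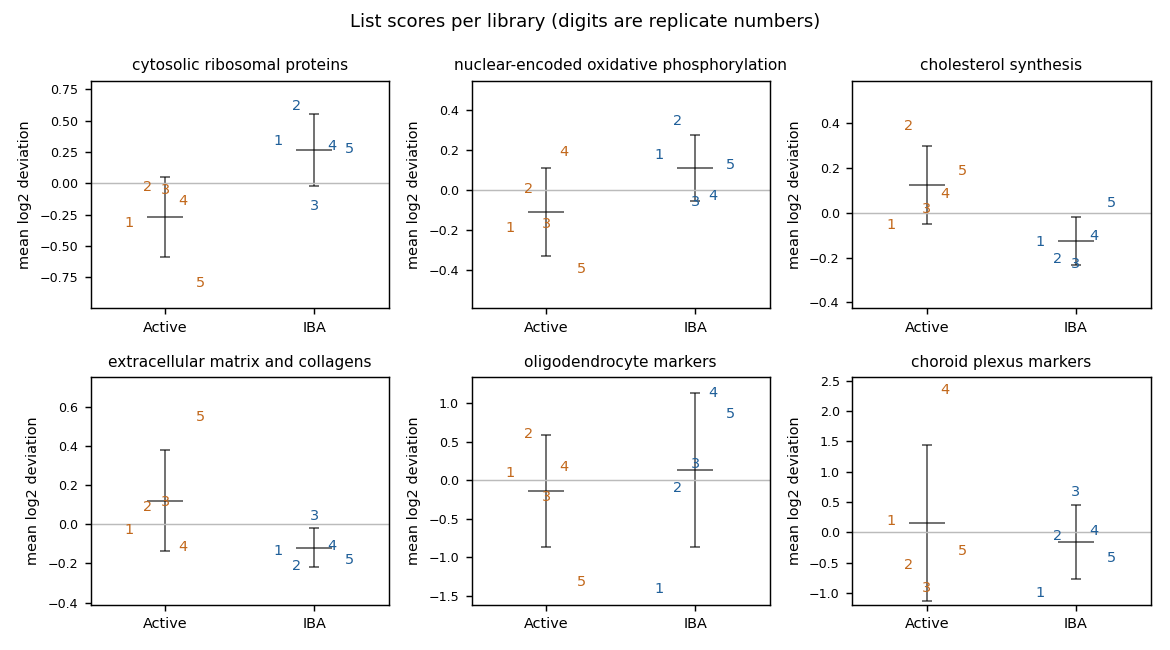
Mean log2 deviation of a list's genes from their means over the 10 libraries (vertical axes, scaled per panel), for the 4 lists called with the preset correlation and for the oligodendrocyte and choroid plexus markers. Digits are replicate numbers, and bars are the mean ± SD of 5 libraries. Active replicate 5 is lowest for ribosomal proteins at -0.80, and Active replicate 4 is highest for choroid plexus markers at 2.36.

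The lists closest to the organ's sensory function were not called by camera. The 11 measured subfornical neuron and thirst genes had a median log2 difference of 0.27, the 8 renin-angiotensin genes one of 0.16 and the 19 genes of osmosensation and water channels one of -0.09 (camera adjusted p = 0.559, 0.637 and 0.867). None of their members passed over all genes tested. Adjusted over the list alone, the counts were 0, 0 and 5, the last with 2 higher and 3 lower. Voltage-gated sodium channels (median 0.16), potassium channels (-0.05), neuropeptides (0.10), synaptic vesicle genes (0.06) and immediate early genes (-0.18) also held no gene past the threshold over all genes. Adjusted over the list alone, the counts were 0, 2, 0, 0 and 2. General markers of neurons and markers of astrocytes, endothelium, pericytes and fibroblasts had medians of 0.16, -0.09, 0.01, -0.21 and -0.18, and camera called none of these lists. The counts adjusted over the list alone were 0 for general neuron and fibroblast markers, 1 higher for GABAergic neurons, 1 higher and 1 lower for hippocampal, septal and thalamic neurons, 1 lower for astrocytes, 1 higher and 1 lower for endothelium, and 3 lower for pericytes. Ependymal markers had a median of -0.08 without a camera call, and 1 was lower when adjusted over the list alone. It was Foxj1, with a log2 difference of -2.06 (adjusted p = 0.0761 over all genes in limma), named after its value was seen.

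The authors' deposited table gave 12 genes at an FDR under 0.05, 8 of them higher and 4 lower in IBA. The denominator degrees of freedom behind the authors' deposited p-values, a median of 22.7 against 14.2 in an edgeR fit of the 10 libraries, leave open whether their model held more libraries than these. Of the 12 genes, 11 were tested here, and all 11 were also called in the same direction, among them Gpnmb, Rbm3 and Asb5. Conversely, 29 of the 62 genes called here had an authors' FDR under 0.1 with the same sign. P2ry12, Tyrobp and Lyve1 had an authors' FDR of 0.225, 0.183 and 0.140. Both analyses used these libraries, so neither is independent support for the other. Sptlc1, a subunit of the enzyme that starts sphingolipid synthesis, had authors' means of 117.3 CPM in Active and 214.1 CPM in IBA in the authors' deposited table. Tbx2, a developmental transcription factor at 0.679 CPM in Active and 0.0992 CPM in IBA in the authors' deposited table, lay under the filter. Both were named after their values were seen. Across the genes tested, which are not independent replicates, the log2 fold changes of limma and of the authors' deposited table had a Pearson correlation of 0.964.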

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

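The tests in this part were chosen after the results were seen, except the comparison of genes of unrelated tissues; several score tests run at first were dropped since their genes had been chosen for the pattern, and the rules of the others were made stricter after their results were seen. There were 5 single-library values far from the other 4 of their state, where chance gives 7.4 among the 148 groups examined. Fos in Active replicate 2 had a log2 value of 6.18 against 4.48 to 4.86 in the others. Trpv4 in Active replicate 4 was at 1.63 against -0.06 to 0.41, in the library with the most choroid plexus markers. Rxfp1 in IBA replicate 5 was at -0.16 against -1 to -0.77. The score of fatty acid oxidation genes in IBA replicate 5 was -0.047 against 0.07 to 0.09, and that of blood cell markers in Active replicate 5 was 0.40 against -0.14 to 0.01.

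Active libraries held reads for more genes, 22810 ± 1525 against 20659 ± 893 in IBA (SD, n = 5 each, two-sided exact permutation p = 0.0397). Deeper sequencing is argued against, since Active libraries were shallower on average and, after thinning all libraries to the depth of the shallowest, Active still held 2129 more genes (exact permutation p = 0.0397). Background reads spread over silent genes may contribute: genes of 5 of 6 unrelated tissues, counted where their mean lay under 2 CPM, had a higher summed mean in Active, where all 6 had been required, and no tissue passed after adjustment. That explanation stays open, because reads outside genes were not analysed here. A difference of state is also open and was not tested.

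Microglia markers tended to higher means and macrophage markers of vessels and meninges to lower means in IBA, though 2 of 10 and 1 of 6 passed over all genes tested in limma. All 6 measured perivascular macrophage markers had lower means, with a median log2 fold change of -0.87. Of 10 parenchymal microglia markers, 8 had higher means, with a median of 0.34. Lyve1, Mrc1 and F13a1, and the microglia members of the fixed list, had been seen before these lists were written. The 2 measured C1q subunits, both lower and also seen before, were held in a list of their own, which raises the share of higher microglia markers. The fixed list of microglia and macrophage markers, which also held Lyve1 and Mrc1, had 7 members higher and 6 lower. A larger share of all macrophage-lineage cells would move both scores together. Over the 3 members of each list not seen before, the difference of the scores changed by 1.02 between states (n = 5 each, two-sided exact permutation p = 0.0159, and 0.0476 adjusted over 3 score tests). That adjustment does not count the score tests that were dropped. The result thus does not settle whether this explanation holds. Less meningeal and vessel-wall tissue stays open: the macrophage score over its 3 unseen members fell by 0.41 beyond fibroblast and pericyte scores, with an exact permutation p of 0.0873. A change in macrophage populations or in their transcription may underlie the pattern, as a hypothesis found and tested on the same libraries, and cell counts were not analysed here.

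Ribosomal protein genes had higher means in IBA, but 0 of 54 passed over all genes tested in limma (47 at an unadjusted p under 0.05), and the list had adjusted p = 0.894 with an estimated correlation, its members being strongly correlated (0.82). Active replicate 5 alone does not account for all of the difference, since without it the median was 0.39 against 0.55 with it. All 54 members were still higher, but members so correlated are not separate support. The list scores of the states overlapped. IBA replicate 3 had -0.18, below Active replicates 2, 3 and 4 at -0.03, -0.06 and -0.14. A shift common to short housekeeping transcripts would move mitochondrial ribosomal protein, proteasome and oxidative phosphorylation scores as much, and the ribosomal score changed by 0.33 more than their mean (exact permutation p = 0.0397, and 0.0595 adjusted over 3 score tests), which leaves it open. RNA integrity, for which no value per library was used here, and the state itself both may also account for it.

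The number of called genes, 62, stood out from splits of the libraries that ignored state. Of 100 splits, 1, the real one, gave as many, and the highest other gave 9. This concerns the number and not which genes were called, and any factor that went with state could give the same result. The number of called lists, 4, did not stand out: 86 of 100 splits gave at least 4 lists, and the highest other gave 16. The 4 called lists had estimated correlations of 0.82 (ribosomal), 0.61 (oxidative phosphorylation), 0.22 (cholesterol) and 0.16 (matrix). These lie above the preset 0.01, so the p-values of camera at the preset correlation may be too small. Whether this is why such splits called many lists was not tested, since they were run at the preset correlation only.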

How the results depend on the processing

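The choroid plexus covariate and the omission of Active replicates 4 and 5 together were chosen after the data were seen. The called genes have no overlap between states, so leaving out libraries cannot turn their direction, and that is no evidence for them. Genes higher and lower in IBA numbered 34 and 28. They were 2 and 4 with no filter (25534 genes), 62 and 59 with sample weights, 596 and 931 in DESeq2 on recovered reads, and 0 and 0 without Active replicates 4 and 5 (2191 genes at an unadjusted p under 0.05 in limma). The lower genes numbered 54 after median-of-ratios scaling and 48 with libraries scaled to the same total. Leaving out one library gave 2 to 70 higher and 2 to 175 lower genes. The causes were not tested. With the replicate block, 81 were higher and 150 lower, but no pairing is established: same-numbered libraries correlated at -0.17 to 0.20, although 3 of 5 Active libraries correlated best with their own number. Lists called numbered 4, 3 to 5 in the other settings and 0 with an estimated correlation.

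Genes that changed sign were not past the threshold. Agtr1 turned to -0.063 without Active replicate 5 and -0.22 without Active replicates 4 and 5, with a high of 0.47 without Active replicate 3. Etv1 turned to -0.023 and -0.081 in the same settings, with a high of 0.19. Fos turned to -0.016 after median-of-ratios scaling, -0.043 with libraries scaled to the same total, -0.17 with sample weights, -0.030, -0.013 and -0.029 with oligodendrocyte, neuron and choroid plexus covariates, -0.16 in edgeR and -0.16 in DESeq2, -0.10 to -0.00 in 6 omissions of one library, and -0.24 without Active replicates 4 and 5, with a high of 0.33 without Active replicate 2; the cause was not tested. Depth limits low genes: 3 reads were worth up to 0.132 CPM.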

Other observations

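All gene lists and tests in this part were chosen after the results were seen. Further called genes were picked after their values were seen, with no test of a shared function. Hspa4l, an Hsp110-family chaperone, fell from 118.7 ± 16.8 to 62.9 ± 14.4 CPM, Fkbp4, an Hsp90 co-chaperone, from 417 ± 47.2 to 277 ± 27.99 CPM, and Ahsa1, an activator of Hsp90, from 190.2 ± 8.42 to 138.5 ± 9.90 CPM (SD, n = 5 each). Hspa13 rose from 90.0 ± 17.7 to 174.8 ± 35.2 CPM. Dbi, which binds acyl-CoA, rose from 138.4 ± 28.1 to 268.0 ± 47.4 CPM, and Eci2, an enzyme of fatty acid oxidation, from 35.1 ± 6.55 to 57.4 ± 4.10 CPM. Clec7a, a receptor for fungal glucans on myeloid cells, rose from 3.70 ± 0.646 to 7.80 ± 1.21 CPM. Fyco1, an adaptor of autophagosome transport, fell from 81.1 ± 3.52 to 44.4 ± 4.23 CPM, and Plod1, a collagen lysyl hydroxylase, from 76.0 ± 5.08 to 39.8 ± 5.27 CPM, both with an adjusted p of 0.00579 in limma.

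Proteasome core genes all had higher means in IBA (14 of 14, median log2 fold change 0.31), with 0 past the threshold over all genes, 9 higher when adjusted over the list alone and p = 0.132 with an estimated correlation in limma's camera. Translation factors had a median of 0.18 (p = 0.182 with an estimated correlation in camera), with 1 of 25 higher over all genes and 6 higher and 1 lower when adjusted over the list alone. Mitochondrial ribosomal proteins had a median of 0.12 (p = 0.543) and the 2 measured C1q subunits one of -0.26 (p = 0.379), each with an estimated correlation. Psma3, Mrpl9, some translation factors such as Eif3e, and the C1q genes had been seen before these lists were written.

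The falls of Hspa4l, Fkbp4 and Ahsa1 raised the hypothesis that chaperones under the heat shock factor HSF1 may be lower in IBA in general. Over 25 such genes outside the fixed list, these 3 included, the median log2 fold change was -0.06 and the mean was -0.16, with 14 lower and 11 higher. At an unadjusted p under 0.05, 8 were lower and 0 higher in limma, and adjusted over the list alone 4 were lower and 0 higher. The 3 genes that raised the hypothesis are in both counts of lower genes, so those counts are not separate support for it. Over all 25, these 3 again included, camera gave p = 0.179 with an estimated correlation, which leaves the hypothesis undecided. The list was not tested without them.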
